A study of Mus musculus with 10 samples.

How the data were processed

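RNA-seq was carried out on the cortex of male mice at 8 weeks of age, with 5 wild-type (WT) libraries and 5 Chd8 knock-in (KI) libraries, each from poly(A) RNA. Groups were taken from the sample titles. Per the submitters' processing notes, the tools used were the read trimmer Trimmomatic 0.39, the aligner HISAT2 2.1.0, the read counter featureCounts 2.0.0 and DESeq2 1.26.0, a package for differential expression, and the genome build was mm10. Their settings, the gene annotation, the use of strand, any filter and the model formula are not given in the sources used here.

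The values analysed here are the authors' deposited table of that 1 comparison, which lists 13661 genes by NCBI gene number. Per-library counts were not analysed here, so the depth of each library is unknown, and no SD, replicate check or test across libraries could be computed. Per the file headers, the authors' table holds for each gene the mean of the normalised counts over all libraries (a signal value, scaled by the authors), the log2 fold change, the standard error of that log2 value, the Wald score and its p-value and adjusted p-value. On checking the deposited columns, the Wald score equalled the log2 fold change divided by its standard error for every gene, and whether the deposited log2 fold changes were shrunken is not given in the sources used here. The deposited adjusted p-value equalled a Benjamini-Hochberg adjustment over the 13660 genes with a p-value. The lowest mean normalised count in the table was 24.4, so weakly expressed genes were not analysed here. The header does not name the direction of the fold change. It was read as KI over WT because Chd8 is higher on that reading, and every direction below rests on this reading.

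The design fixed before the data were examined foresaw a count model if counts were given, and the authors' deposited results if they were not; the second case applied. Fold changes, standard errors and adjusted p-values for single genes are therefore the authors' own, with a threshold of adjusted p under 0.05 and no fold minimum. Intervals are 95% normal intervals from the deposited log2 fold change and standard error. Gene symbols and coordinates came from the RefSeq annotation of GRCm38, the assembly that mm10 is made from. It named 13497 of the gene numbers, GENCODE M21 named 2 more, and 162 stayed without a symbol.

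A family of 38 gene lists (cell types, neighbouring tissues, synapse, ion channels, chromatin, autism risk, signalling, metabolism, stress and RNA quality) was fixed at the same time. The lists hold 903 gene symbols, counting those of a check of sex kept outside the family, and 800 of them were tested. Each list was tested on the deposited Wald scores with cameraPR of limma 3.58.1 in R 4.3.3, a competitive test that compares a list with all other genes, at a preset correlation of 0.01 between members and a minimum of 3 members. Adjusted p-values for lists were computed over the 38 lists. The correlation between members cannot be estimated without per-library values, so preset correlations of 0.05 and, added later, 0.2 were used beside it. A list median was also placed among 10000 random lists of the same size matched on mean normalised count. These were drawn gene by gene, so they do not allow for correlation between members.

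The procedure was tested on simulated data built from the deposited standard errors of the 13660 genes, with 200 genes changed in each of 100 simulations. It recovered 78.7% of genes changed by 0.5 and 97.5% of genes changed by 1 on the log2 scale, and 4.65% of its calls were false. With scores drawn this way a false share near the threshold of 0.05 was built in. The authors' own fit to the counts was not tested. These simulations had independent noise with an SD of 1, whereas the deposited Wald scores had an SD of 0.897 and gave 10 calls. With fewer changed genes the adjusted threshold is stricter, so the recovery in the deposited table may be lower. With no real change and members correlated at 0.2, the list test called 6.9 lists on average at the preset 0.01, 1.91 at 0.05 and 0.06 at 0.2. With members correlated at 0.05 it called 0.62 lists at the preset 0.01.

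The genes named in the text followed a rule fixed in advance: Chd8 and its family, the 8 genes per direction with the smallest adjusted p, the 6 per direction with the largest change among called genes with a mean normalised count of at least 50, the 3 with the smallest p on a side with no call, and up to 4 members per described list. Thumpd3, Bc1 and the neighbours of Chd8 and of the ROSA26 locus were chosen after their values were seen, and the closing observations also name the most abundant markers of each neighbouring tissue. Alternatives were stricter count minimums of 50 and 200, thresholds of 0.1 and 0.01, a minimum log2 change of 0.5, other list correlations, ranks in place of scores, and lists without Chd8. Transcript length and GC content came from the longest GENCODE M21 transcript of each gene, found for 95.9% of genes, and their trends were removed from the Wald score by loess with a span of 0.3. Further marker lists of thalamus, meninges and choroid plexus were written after the first list results were seen and before their own values were.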

Results

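The cortex of adult mice carrying a Chd8 knock-in allele, made as a model of duplication of this autism-related gene, was compared with that of wild-type mice. CHD8 is an ATP-dependent chromatin remodeller of the chromodomain helicase (CHD) family, and its loss-of-function mutations are among the recurrent genetic causes of autism. The series holds 10 libraries, 5 WT and 5 KI, each from a male at 8 weeks of age. Nothing in the labels says whether animals shared a litter. In the authors' deposited table, mean normalised counts ran from 24.4 to 325079.7 with a median of 549, and the median standard error of a log2 fold change was 0.089. The 95% interval lay entirely within ±0.5 on the log2 scale for 88.5% of genes and within ±1 for 99.5%. As a check of the stated sex, the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were all listed in the authors' deposited table, with mean normalised counts of 1470.2, 501, 346 and 740.4 and log2 fold changes from 0.054 to 0.11, none past the threshold. Xist and Tsix, the others of the 6 genes in this check, were not among those tested. Means over all libraries and group fold changes cannot show the sex of each animal.

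Chd8 mRNA rose 1.40-fold in KI cortex in the authors' deposited table (95% interval 1.22 to 1.61; log2 fold change 0.49, standard error 0.10, adjusted p = 0.0044 by the authors' DESeq2 Wald test), with a mean normalised count of 2474 over all libraries. Because the direction of the whole table was read from this gene, its sign is not an independent check, but its size and rank are: it stood 6th by p among 13660 genes. The other 9 CHD genes did not pass the threshold in the authors' deposited table. The closest were Chd3, a NuRD complex remodeller, at a log2 fold change of 0.10 (standard error 0.044, unadjusted p = 0.0215) and Chd9 at 0.21 (standard error 0.12, unadjusted p = 0.0727). Chd4 stood at 0.068 (standard error 0.063), Chd7 at 0.11 (0.11), Chd2 at 0.063 (0.068), Chd6 at 0.073 (0.11), Chd5 at 0.029 (0.078), Chd1 at -0.044 (0.080) and Chd1l at -0.037 (0.12) in the authors' deposited table. The family of 10 was higher as a list (median log2 fold change 0.070, adjusted p = 2.3e-04, cameraPR), with 1 member past the threshold, and also 1 when adjusted over the list alone. With Chd8 the list passed at a preset correlation of 0.05 (0.0023) and not at 0.2 (0.085). The other 9 genes passed as a list at 0.01 (adjusted p = 0.0253) but not at 0.05 (0.0774, a test added after seeing the data). With the transcript length trend removed, the family of 10 passed less strongly at 0.01 (adjusted p = 0.0114, cameraPR). The 9 genes without Chd8 were not tested that way, so length is not excluded for them.

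Over the whole transcriptome, 10 of 13660 genes passed an adjusted p of 0.05 in the authors' deposited table, 1 higher in KI (Chd8) and 9 lower. The gene with the smallest p was Gt(ROSA)26Sor, the non-coding transcript of the ROSA26 locus where transgenes are commonly inserted, which fell to 0.605 of the WT level (95% interval 0.504 to 0.726, adjusted p = 9.6e-04) in the authors' deposited table. The 3 steepest falls there were of Tnnt1, encoding slow skeletal muscle troponin T (0.396 of WT, interval 0.278 to 0.564, adjusted p = 0.0013), Prkcd, encoding protein kinase C delta (0.436, interval 0.296 to 0.643, adjusted p = 0.0437), and Tcf7l2, encoding a transcription factor of the Wnt pathway that marks thalamic neurons (0.528, interval 0.410 to 0.680, adjusted p = 0.0022). Smaller falls in the authors' deposited table were those of Patj, a cell polarity scaffold (0.651 of WT, adjusted p = 0.0457), Ramp3, an accessory protein of calcitonin-family receptors (0.760, adjusted p = 0.0228), Slc5a5, the sodium iodide symporter (0.765, adjusted p = 0.0295), Cntn4, a neuronal adhesion molecule (0.810, adjusted p = 0.0013), and Igf2, an imprinted growth factor made by the meninges (0.815, adjusted p = 0.0022). No gene other than Chd8 passed on the higher side. The 3 with the smallest p there, given as values that did not pass, were Myom3 at a log2 fold change of 0.74 (standard error 0.20, adjusted p = 0.257), Dsp at 0.60 (0.17, adjusted p = 0.39) and Net1 at 0.22 (0.063, adjusted p = 0.436), again from the authors' deposited table. An unadjusted p under 0.05 was given to 440 genes in the authors' deposited table (183 higher, 257 lower), against 683 for uniform p-values. The deposited p-values may thus run too large, for a reason not known here, so the 10 calls may miss changed genes. Tcf7l2, Prkcd and Igf2 stand in lists of markers of thalamus or meninges, and without the genes of those lists and the choroid plexus lists, an alternative chosen after seeing the data, 6 genes passed. Only listed markers were left out, so the falls that remain, Tnnt1 among them, are not shown to be free of neighbouring tissue.

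**Figure D1:**
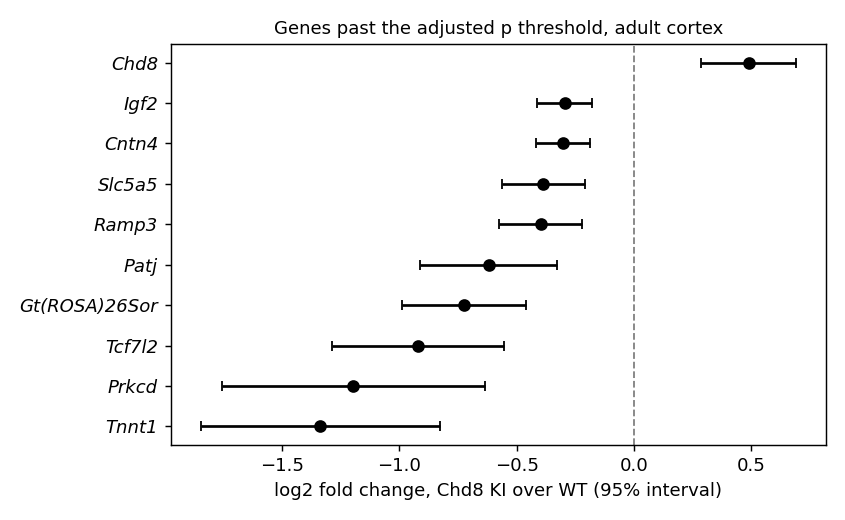
Log2 fold change (x axis, KI over WT) of the 10 genes past an adjusted p of 0.05; points are the deposited estimates and bars their 95% intervals. Chd8 is the 1 gene to the right of 0, and Tnnt1, Prkcd and Tcf7l2 lie farthest to the left.

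In the RefSeq annotation of GRCm38, Chd8 (gene 67772) lies on chromosome 14 from 52198151 to 52258042, and Prkcd (18753) on the same chromosome from 30595353 to 30626414. Gt(ROSA)26Sor (14910), a long non-coding RNA gene, lies on chromosome 6 from 113067428 to 113077244, and overlaps the end of Thumpd3 (113046302 to 113068278). The use of strand in counting is not given, so reads of these genes cannot be told apart where they overlap, and Thumpd3 stood at a log2 fold change of -0.15 (standard error 0.077) in the authors' deposited table. Cntn4 (269784) lies on that chromosome from 105677632 to 106700141. Tnnt1 (21955) lies on chromosome 7 from 4504569 to 4515975 and Igf2 (16002) on chromosome 7 from 142650768 to 142666816. Tcf7l2 (21416) is on chromosome 19 from 55741797 to 55933659, Ramp3 (56089) on chromosome 11 from 6658506 to 6677478, Slc5a5 (114479) on chromosome 8 from 70882885 to 70892785, and Patj (12695) on chromosome 4 from 98395560 to 98719603. The 9 genes other than Gt(ROSA)26Sor are protein-coding, and the values are for whole genes.

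The gene lists showed small shifts shared by many members. Of the 38 lists, 17 passed an adjusted p of 0.05 (cameraPR at a preset correlation of 0.01), 8 higher and 9 lower in KI. The correlation between members could not be estimated without per-library values. At a preset of 0.05 the count was 10, and at 0.2, a value chosen after seeing the data, it was 4. These 4 were the thalamus and hypothalamus, meningeal fibroblast, choroid plexus and ependyma, and mature oligodendrocyte lists, all lower. Correlations above 0.2 were not tried, and markers of the same tissue may be correlated more strongly than that. Passing at 0.2 therefore does not exclude chance variation between dissections for these 4 lists.

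Markers of tissue that adjoins the cortex made up 3 of those 4. The thalamus and hypothalamus list had the lowest median, at a log2 fold change of -0.43 over 13 tested members of 20, of which 10 were negative and 3 positive (adjusted p = 5.0e-12 at 0.01 and 0.0010 at 0.2), with 2 members past the threshold, Tcf7l2 and Prkcd, and 6 lower when adjusted over the list alone. Below the threshold, the authors' deposited table gave log2 fold changes of -0.48 (standard error 0.14) for Plekhg1 and -0.32 (0.11) for Slc17a6, the vesicular glutamate transporter of subcortical neurons. The most abundant member, Hap1, stood at 0.070 in the authors' deposited table. The meningeal fibroblast list, which holds collagens, small proteoglycans and meningeal transporters, had 16 of 16 members with a negative log2 fold change (median -0.24, adjusted p = 5.0e-12 at 0.01 and 0.0016 at 0.2). Its 1 member past the threshold was Igf2, 2 passed when adjusted over the list alone, and the authors' deposited table gave -0.44 (0.14) for Fmod, encoding the proteoglycan fibromodulin, -0.28 (0.11) for Slc13a4 and -0.18 (0.073) for Igfbp2. In the choroid plexus and ependyma list, 12 of 13 members were negative (median -0.19, adjusted p = 8.0e-09 at 0.01 and 0.0049 at 0.2), none passed the threshold and 2 passed when adjusted over the list alone. Its leading members in the authors' deposited table were Kl, encoding klotho, at -0.40 (standard error 0.11, adjusted p = 0.321), Enpp2 at -0.18 (0.059), Kcne2 at -0.51 (0.24) and Folr1 at -0.33 (0.15).

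Mature oligodendrocyte genes were lower as a list as well (16 of 17 members negative, median log2 fold change -0.079, adjusted p = 2.6e-07 at 0.01 and 0.033 at 0.2). None passed the threshold and 1, Enpp2, which the choroid plexus list also holds, passed when adjusted over the list alone. The authors' deposited table gave log2 fold changes of -0.10 (standard error 0.038) for Cnp, -0.16 (0.067) for Mog, encoding a myelin glycoprotein, and -0.16 (0.081) for Fa2h, an enzyme of myelin lipid synthesis. Oligodendrocyte precursor markers had a median of 0.013 (adjusted p = 0.694). Striatal markers were lower at 0.01 (16 of 16 negative, median -0.059, adjusted p = 0.0075; 0.046 at a preset of 0.05 and 0.368 at 0.2), with no member past the threshold either over all genes or when adjusted over the list alone. Its leading members in the authors' deposited table were the dopamine receptor gene Drd1 at -0.14 (standard error 0.10), Ido1 at -0.27 (0.22), Ppp1r1b at -0.091 (0.077) and Penk at -0.14 (0.12). Hippocampal markers were higher at 0.01 (10 of 13 positive, median 0.055, adjusted p = 0.0245; 0.0915 at 0.05 and 0.424 at 0.2), with Dsp alone passing when adjusted over the list alone and Spink8 at 0.35 (standard error 0.19) in the authors' deposited table.

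Synaptic and excitatory neuron lists were shifted upward by a few percent, in the same table in which the thalamic (-0.43), meningeal (-0.24), choroid plexus (-0.19) and oligodendrocyte (-0.079) medians were negative. The postsynaptic scaffold list, which holds the core proteins of the excitatory postsynaptic density, had 20 of 22 members positive (median log2 fold change 0.058, adjusted p = 2.1e-06 at 0.01, 6.6e-04 at 0.05 and 0.087 at 0.2). No member passed the threshold, and none did when adjusted over the list alone. Camk2a, the alpha subunit of the calcium/calmodulin-dependent kinase, stood at 0.12 (standard error 0.042), Dlg2 at 0.10 (0.043), Dlg3 at 0.071 (0.037) and Shank1 at 0.14 (0.082) in the authors' deposited table. A further 4 neuronal or autism-related lists were higher at 0.01 but not at 0.05. These were excitatory neuron markers (median 0.052, adjusted p = 0.0130 at 0.01 and 0.0648 at 0.05), presynaptic vesicle genes (0.041, 0.0166 and 0.102), glutamate receptors (0.044, 0.0298 and 0.149) and autism risk genes (0.037, 0.0141 and 0.190), each given as median and the same 2 adjusted p-values. No member of the first 3 passed the threshold. When adjusted over the list alone, 2 excitatory markers were higher, Nr4a2 at 0.22 (standard error 0.065) and Camk2a, and 1 was lower, Slc17a6, while among receptors Grm3, encoding a group II metabotropic receptor, was higher at 0.18 (0.054), with values from the authors' deposited table. Presynaptic members included Rims2 at 0.085 (0.041) and Vamp1 at -0.10 (0.051) in the authors' deposited table, and none passed when adjusted over the list alone. Among the 71 autism risk genes 53 were positive, yet the 1 that passed, over all genes and when adjusted over the list alone, was Tcf7l2, which fell. The autism risk list was written from memory and is not a database release.

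Nuclear-encoded respiratory chain, unfolded protein response and heat shock lists were lower, as were the thalamic (-0.43), meningeal (-0.24) and choroid plexus (-0.19) medians in the same table. Nuclear-encoded respiratory chain genes had 66 of 71 members negative (median log2 fold change -0.056, adjusted p = 8.7e-07 at 0.01, 0.0052 at 0.05 and 0.311 at 0.2), none past the threshold and none when adjusted over the list alone. Their leading members in the authors' deposited table were Ndufb3 at -0.15 (standard error 0.070), Ndufc1 at -0.19 (0.098), Atp5e at -0.20 (0.11) and Ndufb4 at -0.17 (0.096). The unfolded protein response list was lower too (14 of 19 negative, median -0.085, adjusted p = 3.1e-05 at 0.01, 0.0022 at 0.05 and 0.117 at 0.2), with no member past the threshold on either adjustment. The 4 members with the smallest p, which encode chaperones of the endoplasmic reticulum, were in the authors' deposited table Hsp90b1 at -0.13 (0.046), Calr at -0.16 (0.065), Pdia3 at -0.14 (0.069) and Pdia4 at -0.17 (0.090). Heat shock genes had 15 of 16 members negative (median -0.076, adjusted p = 5.0e-04 at 0.01, 0.0076 at 0.05 and 0.185 at 0.2), with Hsph1 at -0.083 (0.041), Hspe1 at -0.13 (0.078), Hspa8 at -0.095 (0.062) and Cryab at -0.12 (0.079) in the authors' deposited table and none past the threshold on either adjustment. Cytosolic ribosomal protein genes were lower at 0.01 (58 of 76 negative, median -0.030, adjusted p = 0.0473) but not at 0.05 (0.323), and mitochondrially encoded transcripts were higher at 0.01 (11 of 14 positive, median 0.075, adjusted p = 0.0257) but not at 0.05 (0.0974). No member of either list passed on either adjustment. Rps21 stood at -0.13 (0.076) and the mitochondrial ND3 at 0.37 (0.14) in the authors' deposited table.

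Transcript length moved with these lists. Across 13098 genes, which are not independent replicates, the Wald score and the length of the longest transcript had a Spearman correlation of 0.248, and the median length was 6080 bases in the postsynaptic list against 1141 in the respiratory chain list and 1100 in the ribosomal protein list. With the length trend removed, 12 of the 38 lists passed, the postsynaptic, respiratory chain and unfolded protein response lists among them. The autism risk (adjusted p = 0.638), glutamate receptor (0.247), presynaptic vesicle (0.0796) and hippocampal (0.0520) lists then no longer passed, and neither did the ribosomal protein list (0.934), which changed direction.

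**Figure D2:**
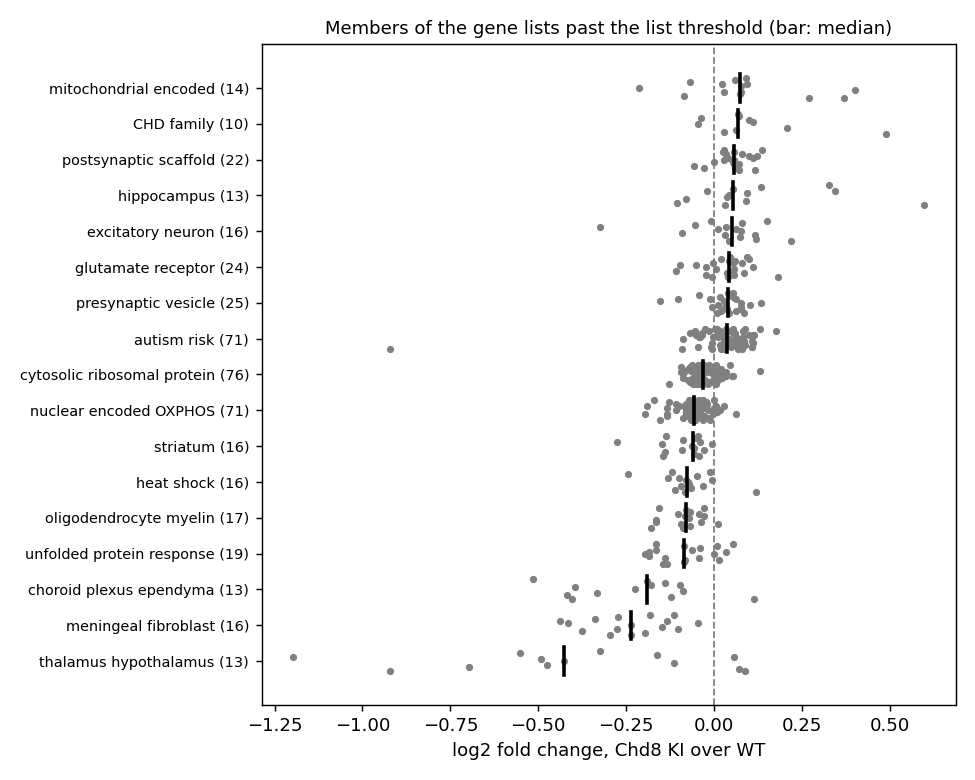
Log2 fold change (x axis, KI over WT) of each tested member (grey points) of the 17 gene lists that passed an adjusted p of 0.05 at a preset correlation of 0.01, with the number of tested members in brackets; black bars are list medians. The medians run from -0.43 for the thalamus and hypothalamus list to 0.075 for mitochondrially encoded transcripts, and vertical offsets of points carry no meaning.

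The other 21 lists did not pass, with adjusted p-values from 0.126 to 0.694 (cameraPR). Cell type markers had median log2 fold changes of -0.038 for inhibitory neurons, -0.0084 for astrocytes, 0.012 for microglia, 0.024 for endothelial cells, -0.028 for mural cells, -0.074 for olfactory bulb and migrating neuroblasts, 0.10 for blood, and 0.013 for oligodendrocyte precursors. GABA receptors had a median of 0.014, receptors for monoamines and acetylcholine -0.022, voltage-gated and related ion channels 0.029, and immediate early genes -0.055. Chromatin regulators outside the CHD family had a median of 0.040, canonical Wnt targets -0.0022, p53 targets -0.040 and cell cycle genes 0.040. Metabolic, immune and hormonal lists had medians of 0.017 for cholesterol synthesis, -0.046 for the interferon response, 0.033 for the circadian clock and 0.015 for glucocorticoid-responsive genes. The replication-dependent histone list, with 3 tested members, had a median of 0.0061 while its mean score was negative. Of the members of these lists, Tcf7l2 among the Wnt targets was the 1 past the threshold. No list among these 21 had any other member that passed when adjusted over the list alone.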

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

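No paired analysis was possible because the deposited table holds no per-library values, and for the same reason leaving out a library, another normalisation, another gene-level test, other pseudocounts, an estimated correlation, fry and other splits of the samples were not run. Alternatives chosen after seeing the data were the correlation of 0.2, genes in 1 list only, the length and GC trends, lists without Chd8 at 0.05, and leaving out neighbouring-tissue genes. A mean normalised count of at least 50 left out none of the 10 called genes, and an adjusted p under 0.1 keeps them by construction and added none, so these 2 settings say little of stability. At a count of at least 200, 7 were called, since Gt(ROSA)26Sor, Tnnt1 and Tcf7l2 lie below it. At an adjusted p under 0.01 the count was 6, with a log2 change of at least 0.5 it was 5 without Chd8, and without the genes of the neighbouring-tissue lists it was 6 (Patj then missed the threshold, and Igf2, Tcf7l2 and Prkcd were left out by construction). Of the 17 lists, 10 passed at a correlation of 0.05, 4 at 0.2, 15 on ranks, 17 without Chd8 (8 at 0.05), 17 at a count of at least 50, 15 with genes in 1 list only, 12 without the length trend and 16 without the GC trend, and each of these had been among the 17. Chd8 stands in the CHD family list alone, so leaving it out could move the other lists only through the adjustment. The count without Chd8 at the main preset therefore says little of their stability. The autism risk, glutamate receptor, presynaptic and hippocampal lists ended with the length trend removed (adjusted p = 0.638, 0.247, 0.0796 and 0.0520). The ribosomal protein list changed direction there (adjusted p = 0.934). Depth per library is unknown, and genes with a mean normalised count under 24.4 were not analysed here.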

Other observations

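The tests around the ROSA26 locus, the thalamic median without Cacna1g and the look at the genes next to Chd8 were chosen after the result was seen, whereas the tests of added markers, transcript length and GC content followed the list results but came before their own values were seen.

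The genes next to Chd8 on chromosome 14 did not share its rise. The 8 tested genes within 250 kb of it, Arhgef40, Zfp219, Hnrnpc, Supt16, Rab2b, Tox4, Mettl3 and Sall2, had log2 fold changes from -0.083 to 0.055 in the authors' deposited table, with a median of -0.016. The highest upper 95% limit among them was 0.20, below the lower limit of 0.29 for Chd8. Bc1, a neuronal non-coding RNA, stood at a log2 fold change of -0.98 (standard error 0.50) in the authors' deposited table and is the 1 gene without a p-value.

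Markers of thalamus, meninges and choroid plexus were lower together in KI cortex, a pattern that less adhering tissue at dissection would give. Of the other adjoining tissues, striatal markers were lower by less: 16 of 16 were negative, with a median of -0.059. That list passed cameraPR at a correlation of 0.01 (adjusted p = 0.0075) and 0.05 (0.046) but not at 0.2 (0.368). Hippocampal markers had a positive median (0.055) and passed at 0.01 (adjusted p = 0.0245) but not at 0.05 (0.0915). They did not pass on ranks (0.0621) or with the length trend removed (0.0520) either. The medians thus differed in size between tissues, but the hippocampal rise is too unsure to set against less adhering tissue. Further markers of thalamus, meninges and choroid plexus, 1 of which (Cacna1g) stands in the fixed ion channel list, were lower as sets. The median log2 fold change was -0.125 over 10 thalamic, -0.138 over 18 meningeal and -0.122 over 13 choroid plexus genes (thalamic median -0.16 without Cacna1g). Among 10000 random lists matched on mean count these lay at percentile 0.01, below every one and at percentile 0.11. Random lists drawn gene by gene ignore correlation between markers. Immediate early genes lay at percentile 0.07 without passing the list test (adjusted p = 0.147, cameraPR). The percentiles therefore do not measure how sure the shifts are, and correlations above 0.2 were not tried in the list test. The most abundant markers went along in part in the authors' deposited table. Slc17a6 stood at -0.32, Igf2 at -0.29, Ptgds at -0.21, Igfbp2 at -0.18 and Enpp2 at -0.18. Apod stood at -0.15, Ttr at -0.12, Cab39l at -0.12 and Slc31a1 at -0.051. By contrast, Hap1 of the mixed thalamus and hypothalamus list stood at 0.070, and the added thalamic markers Cacna1g at -0.035 and Ptpn3 at 0.0052. How much of each comes from cortical cells is not known. Of the fixed lists, 5 of the 13 thalamus and hypothalamus genes and 1 of the 13 choroid plexus genes also stand in another list. Less adhering thalamus, meninges and choroid plexus in the KI dissections may therefore account for the lower markers, including Tcf7l2, Prkcd and Igf2. A genotype effect on those tissues or within cortical cells stays open and untested, because the deposited table does not show which animals carry the shift.

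Postsynaptic genes were higher and respiratory chain genes lower, and the lists differ in transcript length. The difference between the lists in mean Wald score was 1.80, and 1.25 with the length trend removed, where both lists still passed (adjusted p = 2.7e-04 and 0.0079 at a preset correlation of 0.01). The fitted trend thus held part of the difference and not all of it. The length used was that of the longest annotated transcript, not the one expressed in cortex, and only that preset was tried. Length as the whole cause is therefore not excluded. GC content had almost no trend to remove (Spearman -0.022 across genes, a fitted trend from -0.18 to 0.046 in Wald score), so the 1.82 left without it is no test of stability, and the fitted trend itself was small beside the difference. The respiratory chain list did not pass at a correlation of 0.2 (0.311) nor the postsynaptic list (0.087), so correlated members stay open for both, as do genotype and, untested here, a different mix of tissue or cells, which is open for the lower unfolded protein response and heat shock lists too, since thalamic, meningeal, choroid plexus and oligodendrocyte markers were lower in the same table.

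Gt(ROSA)26Sor had the smallest p in the table and Cntn4, called with it, lies 6.88 Mb away on chromosome 6. The labels do not give the insertion site of the knock-in. An insertion at the ROSA26 locus itself, which might lower Gt(ROSA)26Sor directly, is neither shown nor excluded. For changes around that locus, a candidate explanation is DNA of the targeted strain carried along. Among 113 genes within 10 Mb other than Gt(ROSA)26Sor and Cntn4, 8 (7.08%) had an unadjusted p under 0.05 against 3.22% of all genes. They included Washc2 (log2 fold change 0.18), Tmem72 (0.67) and Cntn6 (-0.25) in the authors' deposited table. Without Washc2, Tmem72 and Thumpd3, 5 of 110 (4.55%) did. Washc2 and Tmem72 had been seen before the test was written, and Thumpd3 overlaps Gt(ROSA)26Sor. The mean squared Wald score there was at percentile 97.7 of 13465 windows of the same width, at 91.7 without Washc2 and Tmem72 and at 89.4 without Thumpd3 as well, but these removals from 1 window lower its percentile by construction, and with the 2 genes of smallest p left out of every window it was at 99.3. Carried-over DNA therefore stays open. It cannot be told apart from an effect of genotype, because DNA carried along with the knock-in allele would go with the KI group. The insertion site is also not known, and these values had in part been seen before.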
